A study of Mus musculus with 5 samples.

How the data were processed

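Gene expression was measured on Affymetrix arrays in hearts of mouse embryos at E10.5, with 3 arrays of control hearts and 2 arrays of hearts whose genotype is given as knockout. Per the labels' protocols, total RNA was extracted with Trizol from untreated tissue, and 20 ng was amplified and biotin-labelled with the GeneChip WT Plus kit. The labels number each sample but do not say whether a sample is 1 heart or a pool, so the p-values of single genes below measure the spread between these 5 samples. They do not say whether the controls are wild type or heterozygous.

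The values are log2 expression levels that the authors deposited as 1 table for the whole series. Per the submitters' processing notes, they were made with Affymetrix Expression Console and RMA, which corrects the background of each array, gives all arrays the same distribution and summarises the probes of a set. Versions and settings of these tools are not given in the sources used here. The array medians lay between 5.07 and 5.11 on the log2 scale, and the correlation across all probe sets between any 2 arrays was 0.986 to 0.996. The lowest value was that between the 2 knockout arrays, below each value between a knockout and a control array. No raw scanner values were used, so background could not be judged probe by probe, and the number of arrays limits the precision. The deposited values hold many exact ties, whose source was not tested: 54.8% of the genes tested had an equal value on at least 2 arrays, and 268 had 1 value on all 5.

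Each of the 24479 probe sets carries an Entrez gene number. The platform annotation gives 1 gene symbol for 23281 of them, several for 0 and none for 1198. The numbers of 23156 named sets were found in a RefSeq gene table of assembly GRCm38.p6, from which current symbols were taken. The build behind the array annotation is not given in the sources used here, so the table served for names and gene order and no coordinates are printed. After keeping the brightest probe set of a gene there were 23279 genes. Genes with a mean over the 5 arrays under the 40th percentile (log2 level 4.44) were left out as dim, which left 13967 genes tested and 9312 untested.

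Knockout was compared with control by a linear model per gene in limma 3.58.1 (R 4.3.3; lmFit and eBayes, two-sided), with no covariate and no block, since the sample numbers are not shared between the groups. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. With 2 arrays against 3 there are 10 splits, so no permutation p can fall below 0.1, and the limma model across genes is the test. Gene lists for the embryonic heart, the response to low oxygen and other cell types were fixed before the data were examined, together with a list of the 50 genes on either side of Lrrfip2. Of these 39 lists, 37 had the minimum of 5 tested members. They were tested with camera in limma at its preset correlation of 0.01, which compares a list with all other genes, and adjusted over the 37 lists. At this setting its p-values rest on the spread between genes and do not measure the spread between the 5 samples. Camera with a correlation estimated from the data, camera on ranks, and fry, which tests whether a list's genes move on balance one way, were run beside it. With an estimated correlation, camera also takes its p-values on the 3 residual degrees of freedom of the arrays instead of the number of genes. A call lost there can come from either change. For each list the members passing a threshold adjusted over the list alone were also counted. A list's shift on an array is the median over its genes of the level minus the control mean. The SD of the control shifts was instead taken over each control array's shift from the mean of the other controls. Those are larger than the shifts from the control mean, so a knockout shift within 2 SDs can lie outside the range of the control shifts.

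The genes named are Lrrfip2, up to 12 genes in each direction, up to 4 members of each list with the smallest p, and markers of sex. The 12 per direction were to be those past the adjusted threshold with the largest change. As 0 genes qualified, the places were filled, as the rule provided, by the smallest p among genes with p under 0.01, a fold of at least 1.5 and no overlap between the groups. Gene models without a proper name were passed over (8 of them). Any other gene named was chosen after its values were seen.

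Alternatives concerned the filter on dim genes, the variance prior, array weights, renormalization, centring, averaging of probe sets, unnamed probe sets, thresholds, the level of Y-linked or erythroid genes as a covariate, leaving out sex-linked genes and the neighbours of Lrrfip2, and leaving out each array in turn. Alternatives chosen after seeing the data were the level of endoderm genes as a covariate, the removal of genes with tied values, and a shortened ATF4 list.

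The steps were tested on 20 simulated data sets of the knockout against control comparison, with the means and spreads of the 13967 genes and 200 genes changed. The share of changed genes recovered at the adjusted threshold was 27.1% at 1.5-fold, 58.2% at 2-fold, 87.9% at 4-fold and 97.3% at 8-fold, with 7.35 unchanged genes called per data set. A shifted list was called in 20 of 20 data sets and 0 of 700 tests of unshifted lists gave a call. The simulated genes varied independently, so this does not test the preset correlation. Each gene had the same spread on all simulated arrays. None of these arrays had array-wide differences such as the endoderm transcripts of knockout replicate 2. The recovery shares may therefore not hold for the real arrays.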

Results

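Expression of 23279 genes was read in hearts of mouse embryos at the E10.5 stage, when the looped heart tube is forming its chambers. There were 3 arrays from control embryos and 2 from embryos labelled as knockout. The targeted gene, Lrrfip2, encodes a leucine-rich repeat protein that binds the actin regulator Flii and has been linked to Wnt and toll-like receptor signalling. The title of the series puts the question as one of Lrrfip2 and the response to hypoxia in the forming heart. Levels are log2 RMA values, and differences are knockout minus control.

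Lrrfip2 itself was lower in both knockout arrays. This gene (Entrez 71268) lies on chromosome 9 in GRCm38.p6. Its level was 6.36 and 6.22 in the knockout arrays, and 7.33, 8.07 and 8.08 in control replicates 1, 2 and 3. The log2 difference was -1.54 ± 0.28 (SE), a 2.91-fold lower level, with an adjusted p of 0.355 in limma over all genes. The groups did not overlap, so the values run with the labels. Signal remained on both knockout arrays, above the dim level of 4.44. The sources used here do not give the part of the gene that was deleted, so the probe set may lie partly or wholly outside it, in which case it would not check the genotype.

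Among single genes, the smallest p-values belonged to Hmox1, Hhex and Slc16a10. Hmox1, which degrades haem, had a level of 8.73 ± 0.03 (SD, n = 2) in knockout and 7.61 ± 0.07 (SD, n = 3) in control hearts, a log2 difference of 1.12. The homeobox gene Hhex differed by 1.37, the glutathione-degrading enzyme Chac1 by 1.55 and the vasodilator peptide gene Adm by 1.48. Further genes with higher levels in both knockout arrays were Tmem45a (1.25), the endothelial lectin Clec14a (0.78), Ndrg1 (2.37), the oxygen-sensing prolyl hydroxylase Egln1 (0.85), Apoe (0.89), Car4 (0.69), Sesn2 (0.92) and the mitochondrial serine hydroxymethyltransferase Shmt2 (0.95). Genes with lower levels in both included the aromatic amino acid transporter Slc16a10 (-0.77), the arrestin-like Arrdc4 (-0.94), muscle glycogen phosphorylase Pygm (-0.68), the sarcoplasmic calcium store protein Casq2 (-0.61), the calcium channel subunit Cacna1d (-0.64) and cytochrome c, Cycs (-0.69). The others were Nudt22 (-0.62), Ppp1r1a (-0.62), Nme6 (-0.68), Igfbpl1 (-0.59), Aldh1b1 (-0.73) and Mon1a (-0.72).

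None of these 24 genes, nor any other of the 13967 tested, passed the adjusted threshold in limma: 0 genes were below it, and the smallest adjusted p was 0.287. Exact p-values would by chance put 698.35 genes under an unadjusted 0.05, but in the simulated data 6.19% of unchanged genes were that low. At an unadjusted p under 0.05 there were 1227 genes, 460 with higher and 767 with lower levels in the knockout. With a fold of at least 1.5 as well there were 259, of which 172 were higher and 87 lower; the higher ones numbered 108 without control replicate 3 or with the erythroid level as a covariate, and without knockout replicate 2 there were 467 higher and 390 lower. The groups did not overlap for 2972 genes, or 21.3% of those tested. Chance gives 20% for genes without tied values and no more than that for genes with them. The count of 0 depended on which arrays and genes entered: it was 983 without knockout replicate 2, 9 without knockout replicate 1, 729 with the endoderm level as a covariate and 7 among the genes with 5 different values. In the fits without a knockout array, the single knockout array left is assumed to vary like the controls. The endoderm level is high only in knockout replicate 2, so the fit with it nearly repeats the fit without that array. Of the genes passing without knockout replicate 2, 48.5% had the same direction in knockout replicate 2. That count is therefore not one of changes shared by both knockout arrays.

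Targets of the hypoxia-inducible factors, the transcription factors stabilised when oxygen is low, rose as a group in the knockout hearts. Of 33 tested targets, 32 had higher levels, with a median log2 difference of 1.19 (2.29-fold). While 0 passed over all genes, 27 passed adjusted over the list alone, all of them higher, and 30 had no overlap between groups. They include Egln3 (2.66 ± 0.42, SE), which marks the factors for destruction, Ndrg1 (2.37 ± 0.19), Stc2 (2.14), the collagen prolyl hydroxylases P4ha1 (1.12) and P4ha2 (1.71), and Ankrd37 (1.66). Vegfa, the main growth factor for blood vessels, rose by 1.31 ± 0.16 by the same criterion, the mitophagy receptor Bnip3 by 1.26, the pyruvate dehydrogenase kinase Pdk1 by 0.78 and the glucose transporter Slc2a1, already at a level of 11.5 in controls, by 0.31. The list's shift was 1.46 in knockout replicate 1 and 0.895 in knockout replicate 2, against 0.0122, -0.00151 and -0.0512 in the controls. At its preset correlation camera gave an adjusted p of 1.59e-30, a value that does not measure the spread between samples. The adjusted p = 0.499 with an estimated correlation (unadjusted p = 0.027), and fry gave 0.0306. Knockout replicate 2 also carried transcripts of liver and gut endoderm, with Afp at 11.42 against 3.86 in knockout replicate 1, and both knockout arrays had higher levels of immediate early genes.

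**Figure D1:**
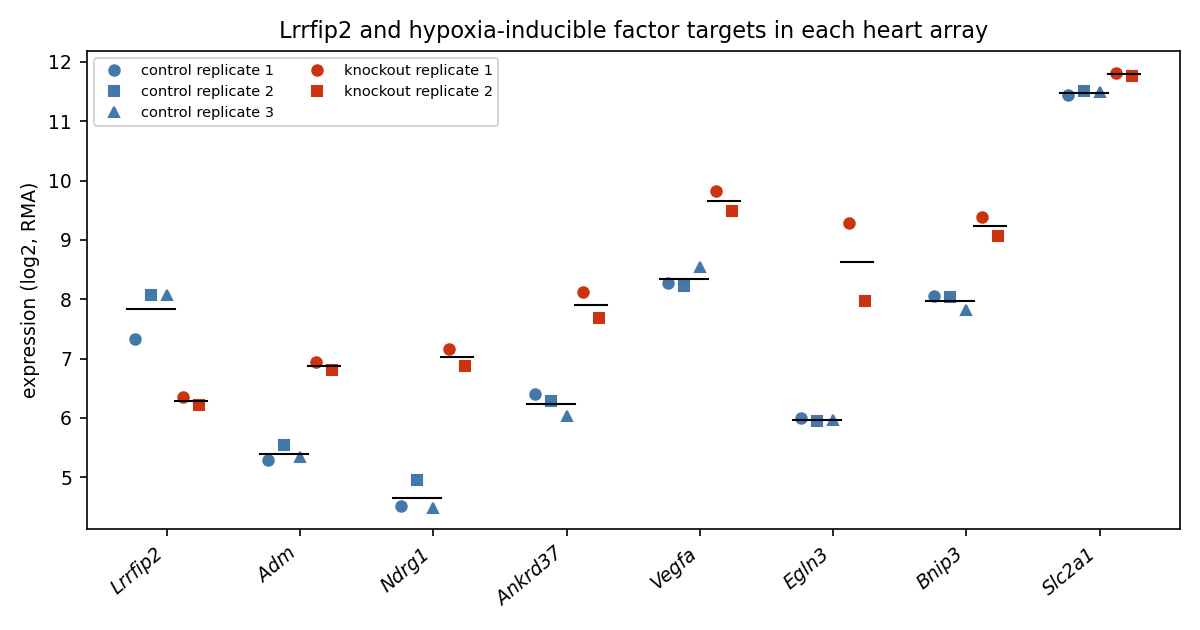
Log2 RMA expression (vertical axis) of Lrrfip2 and 7 hypoxia-inducible factor targets (horizontal axis) on each array; points are arrays, blue for the 3 controls and red for the 2 knockouts, and black lines are group means. Lrrfip2 is at 6.36 and 6.22 in the knockout arrays, below all 3 controls, while each of the 7 targets is higher on both knockout arrays than on any control.

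The separate list of factor subunits and other regulators was not called; the hydroxylase genes Egln1 and Egln3, which rose, are on the target list. Of the 12 tested regulators, among them Hif1an and Egln2, 6 were higher and 6 lower, with a median of 0.02 (camera adjusted p = 0.719). The member with the smallest p, the asparaginyl hydroxylase gene Hif1an (-0.24), did not reach an unadjusted p under 0.05.

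Nuclear genes for the mitochondrial respiratory chain fell together by a small amount. Of 50 subunit genes, 48 had lower levels in the knockout, with a median of -0.17, and the list's shift was -0.162 in knockout replicate 1 and -0.257 in knockout replicate 2. Knockout replicate 2 also carried endoderm transcripts (list shift 3.07) and had lower sarcomere (-0.265) and calcium handling (-0.308) lists. The genes with the smallest p were Atp5o (-0.38) of ATP synthase, the electron carrier Cycs (-0.69), and Ndufb7 (-0.31) and Ndufa8 (-0.27) of complex I. At an unadjusted p under 0.05 there were 18, all lower, and 0 passed adjusted over the list alone. The camera adjusted p was 1.46e-09, and the adjusted p = 0.703 with an estimated correlation.

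Genes of fatty acid oxidation and the tricarboxylic acid cycle fell as a list too, with 23 of 24 lower and a median of -0.18. Dlst (-0.31) and Ogdh (-0.54), both of the oxoglutarate dehydrogenase complex, Etfb (-0.19) and citrate synthase, Cs (-0.22), had the smallest p. The camera adjusted p was 1.64e-04, with an adjusted p = 0.712 with an estimated correlation. The shift was -0.295 in knockout replicate 2 and -0.0633 in knockout replicate 1, and without knockout replicate 2 the adjusted p was 0.29. Knockout replicate 2 also carried endoderm transcripts (list shift 3.07), and with their level as a covariate, chosen after seeing the data, the median was -0.07 with an adjusted p of 0.248. The endoderm level was 6.71 in knockout replicate 2 and 4.30 to 4.36 on the other arrays. This fit therefore nearly repeats leaving that array out and cannot separate endoderm from its other differences. Glycolytic genes rose as a list, with 8 of 12 higher and a median of 0.17 (camera adjusted p = 0.0102, adjusted p = 0.712 with an estimated correlation). Tpi1 (0.31), Pkm (0.32), Pfkl (0.54) and Pfkp (0.80) had an unadjusted p under 0.05. Without knockout replicate 1 the glycolysis call was lost at an adjusted p of 0.425, with a median of 0.15, and without knockout replicate 2 the median was 0.10 with an adjusted p of 0.0318.

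The list of genes of the transcription factor ATF4 and the unfolded protein response rose in the knockout hearts. Of its 28 members, 20 were higher, the median was 0.41, and 11 passed adjusted over the list alone, all of them higher. These were Chac1 (1.55), Ddit4 (1.40), Vegfa (1.31), Trib3 (1.22), asparagine synthetase, Asns (1.15), Shmt2 (0.95), Sesn2 (0.92), Slc3a2 (0.71), Psat1 (0.63), Slc7a5 (0.52) and Atf4 itself (0.33). The unfolded protein response genes on the list, such as Hspa5, Xbp1 and Herpud1, were not among them. At an unadjusted p under 0.05, 1 member of the list was lower. The shift was 0.376 and 0.365 in the knockout arrays, with a camera adjusted p of 1.46e-08. The adjusted p = 0.499 with an estimated correlation, and fry gave 0.0306. Vegfa and Ddit4 are also on the hypoxia list; in a fit chosen after seeing the data, the other 26 genes had a median of 0.29 and a camera adjusted p of 1.03e-06 (adjusted p = 0.703 with an estimated correlation).

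Immediate early and heat shock genes, which respond within minutes to growth signals and to handling of tissue, rose as a list. Of 21, 14 were higher with a median of 0.28, and Ier3 (2.49 ± 0.34, SE) passed adjusted over the list alone. Egr1 (0.44) and Junb (0.34) were higher and the chaperone Hsph1 (-0.69) lower at an unadjusted p under 0.05. The camera adjusted p was 0.00772 and the adjusted p = 0.712 with an estimated correlation. Without knockout replicate 2 the call was lost, with a median of 0.26, near the value over all arrays. With the endoderm level as a covariate, which nearly repeats that fit, the median was 0.25 (camera adjusted p = 0.214). Without control replicate 2 it was 0.16, with an adjusted p of 0.0498. The antioxidant list was not called (17 of 21 lower, median -0.09, adjusted p = 0.18), although Hmox1 and Sesn2 rose and the mitochondrial superoxide dismutase Sod2 fell by 0.45 when adjusted over the list alone. In the p53 and apoptosis list (9 of 19 higher, median -0.04, adjusted p = 0.935), Sesn2 rose and Ccng1 fell by 0.47 by that criterion.

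Genes of DNA replication fell as a list, mostly through knockout replicate 1. All 29 tested S phase genes had lower levels, with a median of -0.22, but the list's shift was -0.407 in knockout replicate 1 and -0.0785 in knockout replicate 2. The latter was within 2 SDs of the control shifts (SD 0.0568), though outside their range, -0.0241 to 0.0421. Without knockout replicate 1 the median was -0.0785. That array also had higher levels of markers of macrophages and other blood cells, with a shift of 0.806. The replication licensing factor Cdc6 (-0.45), Ccne2 (-0.14), the ribonucleotide reductase subunit Rrm2 (-0.90) and Gins1 (-0.36) had the smallest p, 5 genes had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. The camera adjusted p was 1.65e-06 and the adjusted p = 0.712 with an estimated correlation. Genes of G2 and M phase fell as a list, with 24 of 29 lower and a median of -0.12, the mitotic kinase gene Plk1 at -0.42 among them. The shifts were -0.15 and -0.0689 in knockout replicates 1 and 2. Both were within 2 SDs of the control shifts (SD 0.0784), though outside their range, -0.0519 to 0.0526. The camera adjusted p was 0.00683, and the adjusted p = 0.735 with an estimated correlation. That call was lost without control replicate 3 (median -0.08, adjusted p = 0.0933), without knockout replicate 1 (-0.07, 0.107) and with the erythroid level as a covariate (median -0.06, adjusted p = 0.165). Replication-dependent histone genes, 6 of 11 higher with a median of 0.03, were not called (adjusted p = 0.424).

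**Figure D2:**
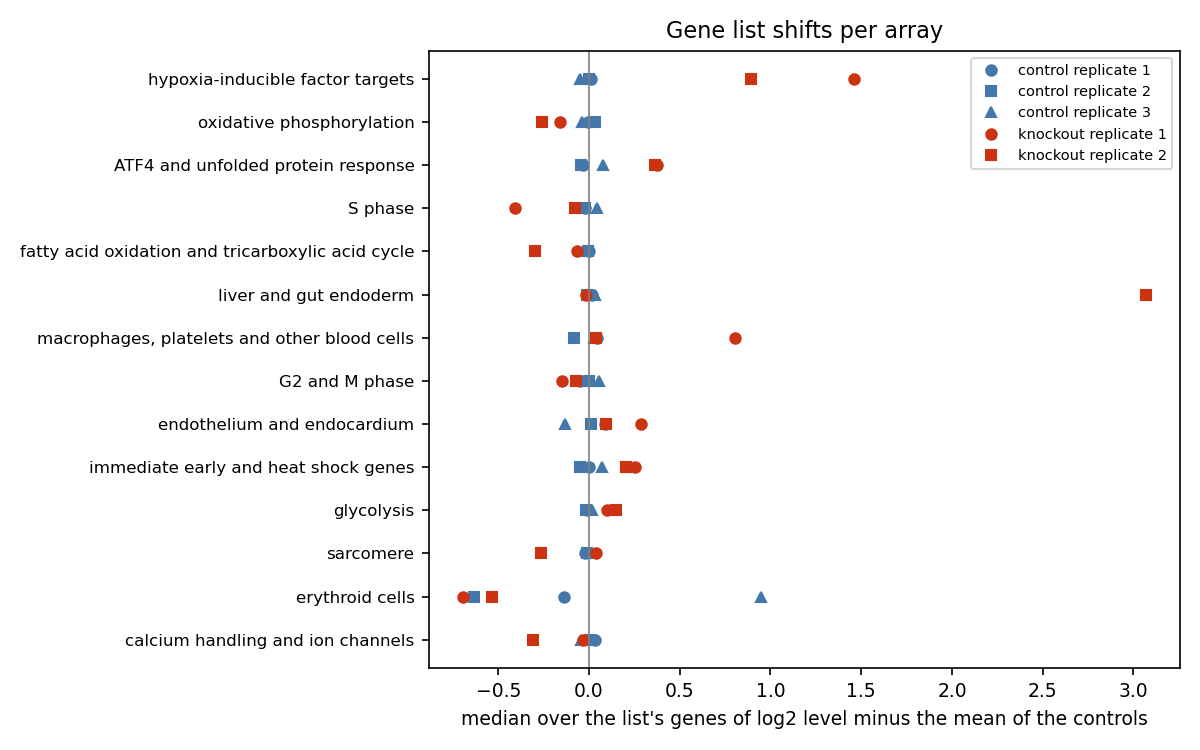
Shift of each of the 14 called gene lists (vertical axis) on each array, as the median over the list's genes of the log2 level minus the control mean (horizontal axis); blue points are the 3 controls and red points the 2 knockouts. Hypoxia-inducible factor targets sit at 1.46 and 0.895 in the knockout arrays, while the liver and gut endoderm list is at 3.07 in knockout replicate 2 and -0.0144 in knockout replicate 1.

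Muscle genes gave a different picture in each knockout array. Of 29 sarcomere genes 23 had lower levels, but the median was -0.06, the shift was 0.0383 in knockout replicate 1 and -0.265 in knockout replicate 2, and the call (camera adjusted p = 0.0133, adjusted p = 0.785 with an estimated correlation) was lost without knockout replicate 2 (0.549). It was also lost without control replicate 3 (median -0.03, adjusted p = 0.0835), after quantile normalization again (-0.03, 0.0777) and with the erythroid level as a covariate (-0.06, 0.0513). Desmin, Des, the muscle intermediate filament, fell by 0.45 and passed adjusted over the list alone; Cryab (-0.33), Xirp1 (-0.41) and Tnnc1 (-0.14) did not. For calcium handling and ion channels, 17 of 22 were lower with a median of -0.12, and Casq2 and Cacna1d passed adjusted over the list alone. The list's shift was -0.0306 and -0.308, its camera adjusted p was 0.0474, and the adjusted p = 0.735 with an estimated correlation. Without knockout replicate 2 the median was -0.03 and the adjusted p 0.552. The call was also lost, with medians of -0.10, -0.09 and -0.10, without control replicate 1 (adjusted p = 0.144), without control replicate 2 (0.0815) and with the Y-linked level as a covariate (0.157), and on ranks (0.0763). The Y-linked level was 7.02 in control replicate 1 and 2.72 to 2.99 on the other arrays, so its fit nearly repeats leaving out control replicate 1. Both lists were lower in the array that carried endoderm transcripts.

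Cardiac transcription factors were not called by camera, with 14 of 21 lower, a median of -0.16 and an adjusted p of 0.169. Fry, which does not compare the list with other genes, gave an adjusted p of 0.0306, downward. The ventricular regulator Irx4 (-0.88), Irx3 (-0.57) and the histone methyltransferase Smyd1 (-0.43) had an unadjusted p under 0.05, and Hand1, at -0.89, did not. Ventricular genes (7 of 11 lower, median -0.08, adjusted p = 0.184), atrial genes (7 of 12 higher, 0.05, adjusted p = 0.664), trabecular genes (8 of 16 higher, median -0.01, adjusted p = 0.602) and compact layer genes (7 of 11 lower, -0.12, adjusted p = 0.274) were not called. Within these, Cited1 was at -0.44, Ccnd2 at -0.18 and the natriuretic peptide gene Nppb at 0.68, each at an unadjusted p under 0.05. Without knockout replicate 1, ventricular and trabecular genes were called lower, at adjusted p of 2.79e-05 and 0.0303; this rests on knockout replicate 2, which carried endoderm transcripts, and the ventricular shift was 0.125 in knockout replicate 1 and -0.323 in knockout replicate 2. Genes of the atrioventricular canal and sinus (9 of 13 lower, -0.12, adjusted p = 0.576), the second heart field and outflow tract (9 of 15 lower, -0.02, adjusted p = 0.866) and the cushion and valve mesenchyme (12 of 23 higher, 0.02, adjusted p = 0.719) were not called either. Cpne5 was at -0.69, Col2a1 at -0.62 and Prrx2 at -0.66.

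Markers of other tissues separated the knockout arrays from each other. Of 16 liver and gut endoderm genes, 15 were higher with a median of 1.58, all of it from knockout replicate 2: Afp was at 11.42 there and between 3.86 and 4.07 on the other 4 arrays, Ttr at 9.96 against 5.43 to 5.48, and Trf at 9.37 against 4.96 to 5.42. The camera adjusted p of 0.00109 became 0.67 without knockout replicate 2, and the adjusted p = 0.735 with an estimated correlation. Markers of macrophages, platelets and other blood cells had a shift of 0.806 in knockout replicate 1 and 0.0394 in knockout replicate 2, with 16 of 18 higher and Mpo, a myeloid enzyme, at 7.67 in knockout replicate 1. Their camera adjusted p was 0.00455, or 0.825 without knockout replicate 1, and the adjusted p = 0.735 with an estimated correlation.

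Red cell genes were lower by a median of -0.62 in 18 of 18 (camera adjusted p = 0.0144, adjusted p = 0.855 with an estimated correlation), but the controls spread from -0.635 in replicate 2 to 0.95 in replicate 3, and the knockout shifts were -0.694 and -0.535. Without control replicate 3 the median was -0.20 and the adjusted p 0.504, and the adjusted p was 0.324 without knockout replicate 1 (median -0.53) and 0.29 without knockout replicate 2 (-0.69). Slc4a1, the red cell anion exchanger, was at 9.34 in control replicate 3 and at 6.82 in control replicate 2. Y-linked signal was found in control replicate 1, with Eif2s3y at 7.70 and Xist, the transcript of the inactive X, at 4.41; on the other 4 arrays Eif2s3y was at 2.37 to 2.68 and Xist at 10.33 to 10.80. Xist was the 1 member of the sex-linked list above the dim level, so that list was not tested.

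**Figure D3:**
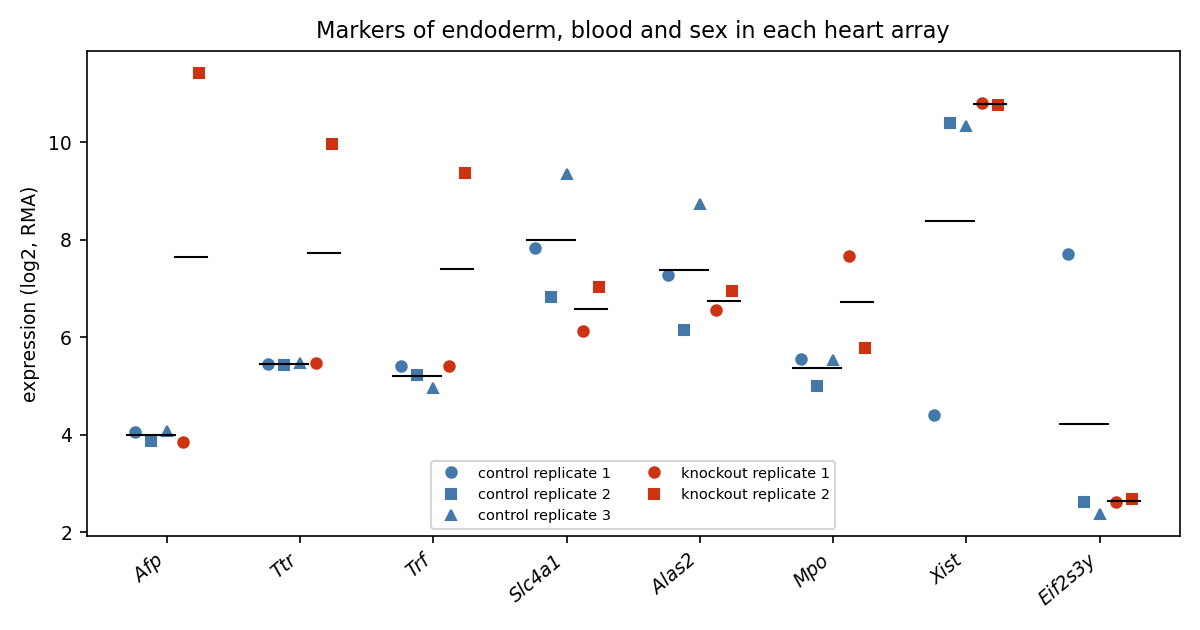
Log2 RMA expression (vertical axis) of markers of endoderm (Afp, Ttr, Trf), red cells (Slc4a1, Alas2), myeloid cells (Mpo) and sex (Xist, Eif2s3y) on each array; points are arrays, blue for the 3 controls and red for the 2 knockouts, and black lines are group means. Afp, Ttr and Trf are high in knockout replicate 2, Mpo is highest in knockout replicate 1, and Eif2s3y is high in control replicate 1.

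Endothelial and endocardial genes rose as a list, with 16 of 24 higher and a median of 0.21. The list's shift was 0.286 in knockout replicate 1 and 0.0925 in knockout replicate 2, both within 2 SDs of the control shifts (SD 0.169). The control shifts ran from -0.132 to 0.0903, the latter in control replicate 1. Knockout replicate 1 also had higher markers of macrophages, platelets and other blood cells (list shift 0.806). The receptor for Vegfa, Kdr (0.60), Sox17 (0.40) and Ets1 (0.64) were higher and the valve regulator Nfatc1 (-0.35) lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. The camera adjusted p was 0.00772 and the adjusted p = 0.735 with an estimated correlation; the call was lost without knockout replicate 1 (median 0.09, camera adjusted p = 0.0948). It was also lost without control replicate 3 (0.22, adjusted p = 0.12) and with the erythroid level as a covariate (0.21, adjusted p = 0.161), where the median was not smaller. Epicardial genes were not called (12 of 19 higher, 0.04, adjusted p = 0.209), although Krt19 was 3.24-fold higher, and without knockout replicate 1, so from the array with endoderm transcripts, they were called higher (9.33e-04). Genes of neural crest and smooth muscle (6 of 10 lower, -0.06, adjusted p = 0.719), neural tissue (6 of 12 lower, -0.02, adjusted p = 0.928) and skeletal muscle and somite (5 of 9 lower, -0.01, adjusted p = 0.866) were not called. Tubb3 of the neural list was at -0.80 and Gap43 at 0.57.

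The signalling themes linked to Lrrfip2 gave no call. Wnt targets had 14 of 19 lower, a median of -0.08 and an adjusted p of 0.719, with Lef1 at -0.85 and Myc at 0.56. They were called lower without knockout replicate 2 (adjusted p = 0.0318) and higher without knockout replicate 1 (0.0435). Toll-like receptor and NF-kappaB genes had 7 of 13 higher, a median of 0.01 and an adjusted p of 0.556, and the relatives and partners of Lrrfip2, Flii (-0.18) among them, 5 of 6 lower, -0.11 and 0.401. Of 26 tested genes next to Lrrfip2, 15 were lower with a median of -0.01 (adjusted p = 0.247), and Nme6 fell by 0.68 when adjusted over the list alone. Imprinted and growth genes (15 of 25 higher, 0.04, adjusted p = 0.203, or 0.00157 without knockout replicate 1, from the array with endoderm transcripts), extracellular matrix genes (15 of 28 lower, -0.03, adjusted p = 0.866) and ribosomal protein genes (14 of 23 lower, -0.16, adjusted p = 0.289) were not called. Mitochondrially encoded genes were not analysed here. The median, the mean and the camera direction differed in sign for 5 lists, none of them called: the factor regulators, cushion mesenchyme, skeletal muscle, p53 and extracellular matrix.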

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

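The tests of a difference in blood content and the leaving out of each array were set before their results were seen; the tests of endoderm tissue, tissue handling, the share of heart muscle cells, the histocompatibility genes and the splits were chosen after them.

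Some probe sets that the comparisons do not use also differed. Of 666 probe sets above the dim level that have no gene symbol here, 12 were higher in both knockout arrays than in all controls at an unadjusted p under 0.05 and a fold of at least 1.5, and 0 were lower by the same criteria. Of the 13967 tested genes, 172 were higher and 87 lower at that p and fold, with overlap allowed. Whether these shares differ was not tested. What the unnamed probe sets measure is not analysed here.

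The rise of hypoxia-inducible factor targets may come from the knockout itself or from the samples. Endoderm tissue in knockout replicate 2 would leave the other knockout array at control level, yet that array had the higher shift, 1.46, and even the smaller one, in replicate 2, was 0.895, where 2 SDs of the control shifts are 0.1. A lower blood content is argued against as the whole cause, since with the erythroid level as a covariate the median was 1.05. Handling of the knockout tissue before lysis remains open: the smaller shift of the immediate early list was 0.206, beyond 2 SDs of its control shifts (0.189), and without knockout replicate 2 that list's median was 0.256 against 0.284 over all arrays, with an adjusted p of 0.263, while without control replicate 2 it was 0.164. A lower oxygen supply in the knockout embryos, or their being at another stage, was not tested; the 5 arrays make 10 splits, too few for a share under 0.05, and the real split had a median of 1.19 (1 split as large), with 0.811 the highest size among the others.

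The fall of respiratory chain genes was seen in both knockout arrays. Endoderm tissue in knockout replicate 2 is argued against by a shift of -0.162 in the array without it, where 2 SDs of the control shifts are 0.11, and a lower blood content by a median of -0.20 (-0.195) with the erythroid level as a covariate. A lower share of heart muscle cells could be the cause in 1 array and cannot be told apart from regulation, because the sarcomere list was at 0.0383 in knockout replicate 1 and at -0.265, like the respiratory list, in knockout replicate 2. An effect of the knockout on mitochondrial genes stays a hypothesis.

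The histocompatibility genes H2-K1 (2.29) and H2-Ab1 (2.44), singled out after their values were seen, were higher in both knockout arrays: H2-K1 was at 8.06 and 7.27 against 5.28 to 5.51, and H2-Ab1 at 9.67 and 8.21 against 6.27 to 6.66. More antigen-presenting cells or an interferon response would raise their partners, but the median over 8 partner genes such as B2m, Tap1 and H2-D1 was 0.0606 with an SD of 0.0979. Other partners, among them Cd74, H2-Aa and H2-Eb1, were too dim to be tested. The macrophage and other blood cell list goes partly the other way. Its shift was 0.806 in knockout replicate 1, where both genes were highest, and 0.0394 in knockout replicate 2. Another histocompatibility haplotype in the knockout embryos, carried along by breeding, may change how well the probes bind and stays open: 1 of the 12 other H2 genes differed by at least 1.5-fold without overlap, against 2.50% of all other genes (Fisher's exact test, two-sided p = 0.263).

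For the number of genes at an unadjusted p under 0.05, 10 splits are again too few for a share under 0.05. The real split gave 1227 and was the 1 split to reach that number. The highest of the others was 873, for control replicate 3 with knockout replicate 1.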

How the results depend on the processing

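The direction of Lrrfip2 was the same under 14 alternatives, from -1.80 to -1.41, with adjusted p from 0.168 to 0.757. The count of 0 changed genes was the same under the other filters, priors, array weights and scalings, without tied genes equal on all 5 arrays, with the Y-linked or erythroid level as a covariate, and at an adjusted p under 0.1. It became 1227 at an unadjusted p under 0.05 and 259 with a fold of at least 1.5 as well. With settings chosen after seeing the data it was 729 with the endoderm level as a covariate, which takes up most of what sets knockout replicate 2 apart, and 7 over the 6307 genes with 5 different values (Adm, Chac1, Hhex, Hmox1, Ndrg1, Ndufa4l2 and Tmem45a), a setting that changes both the variance prior and the number of genes adjusted over; which of these made the calls was not tested. Leaving out 1 array gave 0 to 983 genes: 0 without any control, 9 without knockout replicate 1 and 983 without knockout replicate 2, fits in which the lone knockout array is assumed to vary like the controls. Genes called without knockout replicate 1 included Afp, Ttr and Egln3. Of the genes called without knockout replicate 2, 48.5% had the same direction in knockout replicate 2.

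Of the 14 called lists, those of hypoxia, ATF4, the respiratory chain and S phase were called without each array in turn. The number called was 10 with the erythroid level as a covariate (lost: G2 and M phase, endothelium, sarcomere and red cells). It was 13 with the Y-linked level, on ranks and after quantile normalization, 0 with an estimated correlation, and 10 to 13 without 1 control array. Fry called 3 (hypoxia, ATF4 and, not among the 14, cardiac transcription factors). The fit with the endoderm level called 9, not all among the 14. Without knockout replicate 1, glycolysis, endothelium, red cells, other blood cells and G2 and M phase lost their calls. Wnt, ventricular, trabecular, epicardial and imprinted genes entered instead. Without knockout replicate 2, fatty acid oxidation, sarcomere, calcium handling, red cells, endoderm and immediate early genes lost theirs, and Wnt targets entered. The hypoxia median of 1.19 lost its call in camera with an estimated correlation, 0.319 within the list (adjusted p = 0.499, range over alternatives 5.34e-34 to 0.499). That fit also uses 3 residual degrees of freedom, so the loss cannot be laid to the correlation alone. Cardiac transcription factors, with an estimated correlation of -0.0415, also went from an unadjusted camera p of 0.0687 to 0.14. Without 1 array the hypoxia median was 0.90 to 1.46. Directions reversed for red cells (0.0591) with the erythroid level as a covariate and for endoderm (0.00206) with its own level, by construction. With the endoderm level the sarcomere list reversed to 0.0316 and the camera direction of calcium handling at -0.0312. Without 1 array the sarcomere list ran from -0.265 to 0.0383, calcium handling from -0.308 to -0.0306 and endoderm from -0.0144 to 3.07, where knockout replicate 2 decided.

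Over 175 genes other than Lrrfip2, 2384 of 2450 values under alternatives kept direction and side of the threshold, 58 passed it, 7 took the other sign and 1 was 0. The 58 all came from fits with the endoderm level as a covariate or without a knockout array. Some genes named above, such as Egln3, Vegfa and Afp, are not among the 175. Renormalization left the median difference of all genes at -0.0154 and centring at -0.0269. No paired analysis was possible because the labels give the groups no shared replicate numbers. Signal over background was not analysed here.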

Other observations

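The genes outside the lists that are named here were chosen after their values were seen, and no theme was tested for them. Ndufa4l2, a relative of Ndufa4 that is induced by hypoxia, differed by 2.68 ± 0.30 (SE). Its level was 5.47, 5.56 and 4.93 in the controls and 8.33 and 7.67 in the knockout arrays. Cox4i2, the subunit of cytochrome c oxidase used when oxygen is low, differed by 1.76, in contrast to the small falls of the other respiratory genes. The secreted factors Stc1 (2.24), Igfbp3 (2.21) and Rarres2 (1.96) were higher in both knockout arrays, as were the arginine transporter Slc7a3 (2.11), Nrn1 (2.20), A2m (1.66), Fgf11 (1.65) and Gipr (1.63). None passed the adjusted threshold over all genes.

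On the lower side, outside the lists, Txnip was at -1.01 and its relative Arrdc4, named above, at -0.94; both are known targets of the glucose-sensing factor MondoA. The caveolin of muscle membranes, Cav3 (-1.11), Strip2 (-1.10), Myo16 (-1.15) and Cmtm5 (-1.17) were lower in both knockout arrays, with Cav3 at 5.64 and 5.92 against 6.59 to 7.10. The adult globin gene Hbb-b1 was at -2.18 and Bpgm, which makes the red cell regulator of oxygen binding, at -1.01, in arrays whose red cell lists differed as given in the report. None of these passed the adjusted threshold either.

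Across genes, the shifts of both knockout arrays from the control mean correlated at 0.317. This value contains the shared controls; with a different control array for each knockout array it lay between 0.139 and 0.251 over 6 pairs of controls. Genes are not independent replicates.

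In the endoderm list, 11 of the 16 tested genes were above the dim level in the control hearts, and 0 are on another list. H2-Aa, whose product pairs with that of H2-Ab1, and Cd74 were under the dim level on all 5 arrays, at 2.81 to 2.97 and 4.09 to 4.15.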
